A study of Homo sapiens with 51 samples.

How the data were processed

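RNA from 15 LNCaP libraries, 5 groups of 3, was used; the 36 chromatin immunoprecipitation samples of the series were not analysed here. Each deposited file holds 1 library with 26806 gene rows, and per the file headers gives a fragment count, an FPM value (fragments in rpm) and an FPKM value for each row. The counts are whole numbers as the authors deposited them, without normalization. The deposited FPM, in rpm, divide the count by 1 total per library that is larger than the sum of the gene rows, and the deposited FPKM equal FPM over mRNA length in kb in every row within a relative tolerance of 1e-6. Reads were aligned with STAR 2.5.2b to hg38, per the submitters' processing notes; the counter, the annotation and the strand setting are not given in the sources used here. Coordinates are those of the files (hg38, counted from 1). Libraries held 25563562 to 39145277 fragments in gene rows, and 76.5 to 84.3% of the total behind FPM. Nothing states whether replicates are separate cultures, so p-values measure only the spread between these samples, and the replicate numbers were not taken as pairs.

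Each gene was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the counts, with TMM normalization (factors 0.970 to 1.05), filterByExpr (minimum count 10, minimum total 15), 1 quasi-likelihood fit with a mean per group over all 15 libraries (10 residual degrees of freedom) and two-sided tests with Benjamini-Hochberg adjustment over the 16233 genes kept. The filter left out 10573 rows, and 99.97% of fragments stayed. The common biological coefficient of variation was 0.0834. Genes with an adjusted p under 0.05 were called. A plan for FPKM with limma was set for files without counts; since the files hold counts, its stated branch with edgeR was used, and limma on FPKM became an alternative. The SE of a log2 fold change was its size over the square root of F. Levels are CPM with TMM-scaled library sizes. Folds against a group without any fragment are bounds computed at a floor of 3 fragments over the group, and intervals for ratios of small counts have a confidence level of 95%; both cover counting error only. In simulated data with 200 changed genes per comparison, 76.1 to 89.6% of 2-fold changes were recovered, and 1.79 to 10.5% of called genes were false. The simulated counts varied independently between genes, without an axis of variation shared by libraries, and few genes changed. These rates may therefore not carry over to the real comparisons.

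The comparisons, main tests, first alternatives, gene lists and naming rule were chosen before the data were examined. The residual factor, the gene length correction, the leaving out of 3 libraries and the share of the fall under interferon were added after seeing the data, as were the tests of the library that stands apart, of list members called in other splits, of the type I fall with STAT2 siRNA and of the interferon effect on the cell cycle. The 19 lists cover type I interferon response, interferon signalling components, MHC class I antigen presentation, interferon gamma type genes, chemokines and NF-kB targets, immune checkpoint ligands, androgen-regulated genes, luminal prostate identity, basal and mesenchymal genes, neuroendocrine genes, cell cycle, p53 targets, cell death, endoplasmic reticulum stress and amino acid response, cholesterol and lipid synthesis, hypoxia and glycolysis, the pioneer factor family, other cell types and mitochondrial transcripts. None of the 13 mitochondrial transcripts was in the files, so 18 lists were tested; the neuroendocrine and pioneer lists share 1 gene. Lists were tested with camera (preset inter-gene correlation of 0.01, and an estimated correlation beside it) and adjusted over the lists of a comparison; lists were not tested with DESeq2, so their ranges over alternatives leave it out; members were counted over all genes tested and adjusted over the list alone. Named genes are FOXA1 and STAT2; the 10 largest increases and decreases among called genes with a mean of at least 1 FPKM in the higher group, a symbol that is no clone or locus identifier and libraries that do not overlap between the groups (for the interaction, without this last condition); from each list the 4 smallest adjusted p and the 4 highest mean FPKM, with any member of the type I, signalling, MHC class I, checkpoint and androgen-regulated gene lists; and the 10 genes of each direction of the reversal with the largest smaller change. Symbols are those of the files, and some genes that this rule selects are not reported here.

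Alternatives were median-ratio scaling, DESeq2 1.42.0 without a count filter, no filter, a mean of at least 5 FPKM, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, on TPM and on quantile-normalised values, replicate number as a block, a fit of the compared groups only, an estimated inter-gene correlation, a fold threshold in the reversal and leaving out each library in turn. Other splits of the libraries into groups of the same sizes were counted, all 10 for 3 against 3 and 100 for the interaction and the reversal. FOXA1 and STAT2 FPKM were compared with exact two-sided permutation tests. For 414 symbols with more than 1 row, 533 further rows were kept as separate rows.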

Results

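RNA was sequenced from 15 libraries of LNCaP cells, a human prostate cancer line, in 5 groups of 3. Cells received a control siRNA (siCon) or an siRNA against FOXA1 (siFOXA1), a forkhead pioneer factor that opens chromatin for other transcription factors, and were then kept in vehicle or given 100 ng/L interferon alpha (IFNa), a type I interferon, for 24 h. The fifth group, siFOXA1+siSTAT2+IFNa, received siRNAs against FOXA1 and STAT2 together with interferon; STAT2 is, with IRF9, part of the transcription factor complex that type I interferon activates. There was no group with the STAT2 siRNA alone, so effects of that siRNA were measured only on top of FOXA1 siRNA and interferon. The 36 chromatin immunoprecipitation samples of the series were not analysed here. Each library held 25563562 to 39145277 fragments in gene rows, and 16233 genes were tested. Ribosomal protein genes took 11.9 ± 0.388% of fragments in siCon, 8.97 ± 0.144% in siFOXA1, 10.6 ± 0.405% in siCon+IFNa, 8.33 ± 0.0992% in siFOXA1+IFNa and 11.4 ± 0.312% in siFOXA1+siSTAT2+IFNa (SD, n = 3 each). The share of the total behind FPM that lay in gene rows also moved with the treatments, at 77.0 ± 0.465%, 82.1 ± 0.228%, 80.6 ± 0.413%, 84.2 ± 0.106% and 79.3 ± 0.593% in the same order, and ribosomal RNA rows took 1.70 ± 0.0640%, 2.04 ± 0.0110%, 1.80 ± 0.0894%, 2.21 ± 0.0683% and 2.13 ± 0.145%. The comparisons below were not corrected for these shares. Levels are given as mean CPM ± SD with n = 3, and changes as log2 fold change ± SE from edgeR with the adjusted p.

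The siRNA targets were measured first. FOXA1 (chromosome 14, 37589552 to 37595120 on hg38) had 77.0 ± 2.65 FPKM in siCon and 23.9 ± 1.15 in siFOXA1, which is 31% of the siCon mean (SD, n = 3). Under interferon FOXA1 had 91.5 ± 3.94 FPKM in siCon+IFNa, 22.9 ± 0.422 in siFOXA1+IFNa and 31.2 ± 1.01 in siFOXA1+siSTAT2+IFNa (SD, n = 3). FOXA1 thus fell with its siRNA by 1.70 ± 0.06 on the log2 scale without interferon and by 2.06 ± 0.06 with it, and was 0.53 ± 0.06 higher when STAT2 siRNA was added (adjusted p = 9.62e-06). STAT2 (chromosome 12, 56341598 to 56360253) had 16.1 ± 0.529 FPKM in siCon, 13.2 ± 0.340 in siFOXA1, 17.6 ± 0.436 in siCon+IFNa, 17.1 ± 0.853 in siFOXA1+IFNa and 10.1 ± 0.149 in siFOXA1+siSTAT2+IFNa (SD, n = 3). With STAT2 siRNA, STAT2 fell by 0.67 ± 0.05 against siFOXA1+IFNa (adjusted p = 7.49e-08), and 57.7% of the siCon+IFNa level was left. Exact two-sided permutation tests of 3 against 3 libraries gave p = 0.1 for each of these knockdowns, the smallest value this group size allows. Interferon raised FOXA1 in siCon cells by 0.24 ± 0.06 (adjusted p = 0.0226), but this call was lost when 1 library was left out: the adjusted p was 0.114 without siCon replicate 2, 0.0952 without siCon replicate 3 and 0.0835 without siCon+IFNa replicate 2, within a range of 3.66e-12 to 0.141 over all alternatives.

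**Figure D1:**
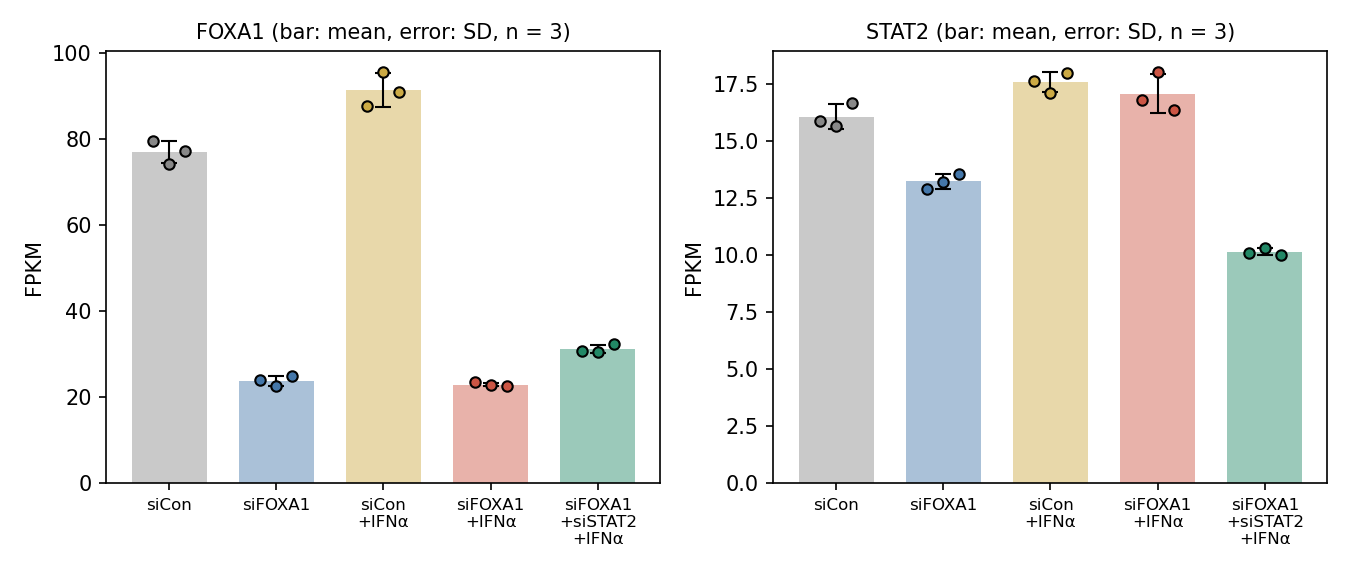
FPKM of FOXA1 and STAT2 (vertical axes, from 0) in the 5 groups; bars are means, error bars are SD and points are the 3 libraries of each group. FOXA1 stands at 23.9, 22.9 and 31.2 FPKM in the 3 groups with FOXA1 siRNA, and STAT2 is at 10.1 FPKM in the group with STAT2 siRNA.

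The first comparison, siFOXA1 against siCon, asks which genes depend on FOXA1 in unstimulated cells. Over all 16233 genes tested 62.3% were called in it, 48.6% of these higher, so counts of called list members stand beside that share. All 36 tested cell cycle genes were lower after FOXA1 siRNA, with a median log2 fold change of -1.91. MKI67, a nuclear antigen of dividing cells, dropped from 36.7 ± 1.34 to 6.67 ± 0.355 CPM, and RRM2, a ribonucleotide reductase subunit, fell by 3.12 ± 0.13 on the log2 scale. CDC20, an activator of the anaphase-promoting complex, and TOP2A, the topoisomerase of dividing cells, changed by -2.52 and -2.40. In the basal and mesenchymal list 14 of 17 genes rose and 2 fell, with a median of 1.45. FN1, fibronectin, went from 98.2 ± 0.628 to 713 ± 2.04 CPM (2.86 ± 0.04), SNAI2, a repressor of epithelial genes, rose by 3.75 ± 0.18 and IL1R1, an interleukin 1 receptor, by 1.89 ± 0.06; ITGA5 (-1.31) and AXL (-1.71), named after their values were seen, fell. The chemokine and NF-kB list had 12 of 17 genes higher and 2 lower, among them IL1B (4.70 ± 0.36), TRAF1 (3.43 ± 0.24) and the NF-kB inhibitor NFKBIA (1.17 ± 0.06), whereas CXCL16 fell (-0.52). In the camera test of each list against the other genes, the adjusted p was 1.51e-21 for the cell cycle list (0.000367 with an estimated correlation), 1.37e-07 for the basal and mesenchymal list (0.00117) and 0.00283 for the chemokine list (0.0221).

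Genes of the prostate moved both ways, as called genes did at large. Of 40 androgen-regulated genes 18 rose and 19 fell. The kallikrein KLK3, which encodes prostate-specific antigen, went from 94.9 ± 5.66 to 479 ± 7.11 CPM (2.34 ± 0.07), and KLK2 (1.36) and FKBP5, a glucocorticoid receptor cochaperone, (2.33) rose as well. SLC45A3, the prostein gene, dropped from 385 ± 21.3 to 7.80 ± 0.672 CPM (-5.63 ± 0.12), and ACPP, prostatic acid phosphatase, (-2.56) and TMPRSS2 (-0.79) also fell. A luminal list had 12 of 24 genes higher and 7 lower, with GRHL2 (1.31) up and, in the other direction, AGR2 (-2.80) and the splicing factor ESRP2 (-1.15). Neither list passed the camera test against the other genes (adjusted p = 0.146 and 0.529). Of 8 forkhead and hepatocyte factor genes 5 fell and 2 rose, with FOXP1 (-2.60) and FOXM1 (-2.09) down beside FOXA1, the siRNA target, and FOXO3 (1.06) up. The adjusted p of 0.0253 became an adjusted p of 0.0690 with an estimated correlation, in a range of 0.0142 to 0.527 over all alternatives. The fall of FOXA1 restates the knockdown, and this list was not tested without it here or in the comparisons below. In the endoplasmic reticulum stress and amino acid list 12 of 20 genes fell and 2 rose, among them the stress transcription factor DDIT3 (-0.99), with DDIT4 (-0.85) and TRIB3 (-0.83), and adjusted p = 0.00523 (0.0240 with an estimated correlation).

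Without interferon, 23 of 64 type I interferon genes rose after FOXA1 siRNA and 19 fell, with a median of 0.11. Calls in both directions are not particular to this list, since 62.3% of all genes were called in this comparison, 48.6% of these higher. The list did not pass the camera test against the other genes (adjusted p = 0.948). OAS1, an antiviral oligoadenylate synthetase, rose by 2.37 ± 0.11, whereas IFIT2 (-1.10), DHX58 (-1.10) and HERC5 (-0.97) fell. Of the MHC class I list 7 of 21 genes rose and 4 fell, with the peptide transporter TAP2 (-1.70) and the peptidase ERAP2 (-1.68) lower and HLA-E (0.53) higher (adjusted p = 0.878). STAT3 rose by 1.33 ± 0.04 and IRF1 fell by 1.09, in a signalling list with 6 of 17 genes higher and 3 lower. That list had a median of -0.03 but a mean of 0.25 and an upward test (adjusted p = 0.493). The interferon gamma list had 8 of 14 genes higher and 3 lower, with GBP2 (2.36) up and HLA-DMB (-3.68) down (adjusted p = 0.529). Of 12 checkpoint ligand genes 7 rose and 2 fell, with CD47 (1.41) up and CD274, which encodes PD-L1, (-1.55) down (adjusted p = 0.557).

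None of the other lists passed the camera test against the other genes after FOXA1 siRNA. The p53 list had 3 of 20 genes higher and 12 lower (adjusted p = 0.493), with GDF15 (-2.16) down and RRM2B (0.92) up, and the cell death list had 8 of 22 higher and 7 lower (0.636), with BMF (-1.63) down. The cholesterol list had 9 of 22 higher and 4 lower (0.636), and the hypoxia list 7 of 16 higher and 5 lower (0.996), with ALDOA (1.34) up and HK2 (-0.84) down. The neuroendocrine list had 2 of 9 higher, SYT4 (4.44) and ENO2 (0.63), and 4 lower; its median was -0.24 although its test pointed up (0.636). Of 5 markers of other cell types 2 rose, CD68 (1.18) and COL3A1 (1.85), and 2 fell, VWF (-1.48) and PDGFRB (-2.56) (adjusted p = 0.933). Adjusted over the list alone the counts were equal, except for 20 lower androgen-regulated genes, 4 higher p53 genes and 8 higher hypoxia genes.

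Among single genes, the largest increases included CAMK2N1, an inhibitor of calcium/calmodulin kinase II, from 6.93 ± 0.359 to 440 ± 12.0 CPM, SERPINA5, a serine protease inhibitor, (7.21 ± 0.25), TMEM100 (7.99 ± 0.28), PGLYRP2 (6.60 ± 0.37) and CD22 (6.41 ± 0.21). Over the 3 siCon libraries SERPINA5 held 7 fragments, TMEM100 6, PGLYRP2 7 and CD22 9. The sizes of these increases therefore rest on few fragments. The keratin KRT16 (chromosome 17, 41609779 to 41612827) had no fragment in the 3 siCon libraries and was at least 81.4-fold higher after FOXA1 siRNA, against a floor of 3 fragments over the group; the antimicrobial peptide gene CAMP was at least 48.9-fold higher. The largest decreases included the glucuronosyltransferase UGT2B11, from 152 ± 10.5 to 1.16 ± 0.315 CPM, APOF (-6.00 ± 0.23) and WWTR1, a Hippo pathway coactivator, (-7.64 ± 0.28). Over the 3 siFOXA1 libraries APOF held 10 fragments and WWTR1 6, so the sizes of these decreases rest on few fragments as well. UGT2B4 was at least 98.8-fold lower. The UGT2B and kallikrein genes have close paralogs, and how fragments shared between such genes were counted is not given in the sources used here. In all 10117 genes were called, 4912 higher and 5205 lower, of which 1581 and 1540 differed at least 2-fold; which direction held more depended on the scaling (4565 higher and 3905 lower on TPM).

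The second comparison, siCon+IFNa against siCon, measures the interferon response of cells with FOXA1. Of the 64 type I interferon genes 50 rose and 1, DHX58, fell (-0.55), with a median of 0.95 and adjusted p = 8.32e-169 (1.62e-10 with an estimated correlation). IFIT1, an antiviral RNA-binding protein, went from 3.66 ± 1.38 to 83.1 ± 11.4 CPM (4.50 ± 0.17). SAMD9 rose by 3.74 ± 0.19, IFIT2 by 3.71 ± 0.10, OAS1 by 3.65 ± 0.10, IFIT3 by 3.43 ± 0.15, RSAD2, the antiviral enzyme viperin, by 2.81 ± 0.15, IFI6 by 2.76 ± 0.07, OASL by 2.61 ± 0.12 and OAS3 by 2.49 ± 0.11, as did DDX58, which encodes the RNA sensor RIG-I (2.49 ± 0.12). ISG15, a ubiquitin-like modifier, was at 8.21 ± 2.41 and 14.03 ± 5.34 CPM and did not pass (adjusted p = 0.108). Among the 17 signalling genes IRF9 (1.31 ± 0.11) and STAT3 (0.18) rose and TYK2 fell (-0.52), with a list adjusted p of 0.00981. With an estimated correlation the list did not pass, at an adjusted p of 0.050 just above the threshold. Of 21 MHC class I genes 3 rose, PSMB9 (1.51 ± 0.34), TAP1 (0.33) and CANX (0.22), and none fell (list adjusted p = 0.412). Of 12 checkpoint ligand genes LGALS9, galectin 9, (2.92 ± 0.58) and CD274 (0.77 ± 0.17) rose (list adjusted p = 0.661). TAP1 lost the call without siCon replicate 1 (adjusted p = 0.0544), siCon replicate 3 (0.0710), siCon+IFNa replicate 1 (0.0815) or siCon+IFNa replicate 3 (0.0693), with 5.4e-08 to 0.235 over all alternatives. CANX lost the call without siCon replicate 2 (adjusted p = 0.187), siCon replicate 3 (0.176) or siCon+IFNa replicate 2 (0.181), with 3.72e-13 to 0.193 over all alternatives. CD274 lost the call without siCon replicate 2 (adjusted p = 0.0812) or siCon+IFNa replicate 2 (0.0625), with 3.72e-05 to 0.126 over all alternatives. DHX58 lost the call without siCon replicate 2 (adjusted p = 0.215), siCon replicate 3 (0.110), siCon+IFNa replicate 1 (0.105) or siCon+IFNa replicate 2 (0.168), with 0.00459 to 0.215 over all alternatives. PSMB9 lost the call without siCon replicate 2 (adjusted p = 0.0745) or siCon replicate 3 (0.0504), with 9.75e-05 to 0.0865 over all alternatives. TYK2 lost the call without siCon replicate 2 (adjusted p = 0.0660) or siCon replicate 3 (0.0715), with 3.57e-12 to 0.121 over all alternatives. STAT3 lost the call without siCon replicate 3 (adjusted p = 0.0734), with 1.4e-07 to 0.197 over all alternatives. ISG15 passed without siCon+IFNa replicate 2 (adjusted p = 0.0369), with 3.33e-12 to 0.307 over all alternatives. The signalling list lost the call without siCon+IFNa replicate 3 (adjusted p = 0.0618), with 0.000452 to 0.196 over all alternatives.

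Few other groups moved with interferon in control cells. Of 22 cell death genes 3 rose, such as TNFSF10, the death ligand TRAIL, (1.72 ± 0.20) and MCL1 (0.36), and GSDMB fell (-0.53); the list adjusted p was 0.0259 (adjusted p = 0.219 with an estimated correlation). Of 40 androgen-regulated genes 6 rose, such as MAF (0.41), and TMPRSS2 (-0.51), KLK2 (-0.43) and KLK3 (-0.26) fell. Of 36 cell cycle genes KIF11 alone was called (0.36, adjusted over all genes), and of 20 stress genes none. With p adjusted over the list alone, 53 type I genes rose and 2 fell, and 5 signalling genes rose and 2 fell. Genome-wide 1721 genes were called, 1131 higher and 590 lower, of which 44 and 27 differed at least 2-fold. This count depended on single libraries: it was 3439 without siCon replicate 1, 382 without siCon replicate 2, 375 without siCon replicate 3 and 762 without siCon+IFNa replicate 2. In a fit of the compared libraries alone it was 70. The largest decreases included NPPA (-1.10 ± 0.26) and ATHL1 (-1.06 ± 0.19). The cell death list lost the call without siCon replicate 1 (adjusted p = 0.0843) or siCon+IFNa replicate 3 (0.0959), with 0.00227 to 0.466 over all alternatives. NPPA lost the call without siCon replicate 2 (adjusted p = 0.0776), siCon replicate 3 (0.0584) or siCon+IFNa replicate 2 (0.0568), with 0.00168 to 0.0985 over all alternatives. GSDMB lost the call without siCon replicate 2 (adjusted p = 0.146), siCon replicate 3 (0.0644), siCon+IFNa replicate 1 (0.0587) or siCon+IFNa replicate 2 (0.0941), with 4.5e-05 to 0.146 over all alternatives. KIF11 lost the call without siCon replicate 2 (adjusted p = 0.175), siCon replicate 3 (0.138), siCon+IFNa replicate 1 (0.0656) or siCon+IFNa replicate 2 (0.174), with 6.94e-05 to 0.175 over all alternatives. KLK3 lost the call without siCon replicate 2 (adjusted p = 0.0800), siCon replicate 3 (0.110) or siCon+IFNa replicate 2 (0.0732), with 6.07e-11 to 0.151 over all alternatives. MCL1 lost the call without siCon replicate 2 (adjusted p = 0.0661) or siCon replicate 3 (0.0734), with 2.85e-19 to 0.125 over all alternatives.

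The third comparison, siFOXA1+IFNa against siFOXA1, measures the interferon response after FOXA1 siRNA. Of the 64 type I interferon genes 61 rose and none fell, with a median of 1.65 and adjusted p = 1.35e-319 (1.3e-11 with an estimated correlation). IFI27 went from 0.998 ± 0.0952 to 33.9 ± 4.16 CPM, IFITM1, which restricts virus entry, from 1.75 ± 0.474 to 43.4 ± 6.22, and ISG15 from 10.4 ± 2.75 to 105 ± 23.6 (3.33 ± 0.30). OAS2 rose by 7.23 ± 0.26, IFI44L by 5.48 ± 0.19, IFIT2 by 5.14 ± 0.11, BST2, the virus tether tetherin, by 4.92 ± 0.25, IFIT1 by 4.88 ± 0.16 and IFI6 by 4.57 ± 0.07. XAF1 had 2 fragments in siFOXA1 and a log2 change of 8.92, with a counting interval of 158 to 4730-fold. In the signalling list 7 of 17 genes rose and 2 fell, with IRF9 (2.30 ± 0.11), IRF7 (1.18 ± 0.23) and STAT2 (0.30 ± 0.05) up and JAK1 (-0.33) and PTPN2 (-0.22) down (adjusted p = 1.14e-05, and 0.00291 with an estimated correlation). In the MHC class I list 13 of 21 genes rose and none fell, among them HLA-B (1.12 ± 0.08), HLA-C (0.86 ± 0.11), the immunoproteasome subunit PSMB9 (2.12 ± 0.28) and NLRC5, an activator of MHC class I genes, (0.72 ± 0.14) (adjusted p = 7.98e-11, and 0.00212). Of 14 interferon gamma genes 6 rose and none fell, led by GBP4 (3.26 ± 0.27), with adjusted p = 4.63e-06 (0.00462). JAK1 lost the call without siFOXA1 replicate 1 (adjusted p = 0.149), siFOXA1 replicate 2 (0.111), siFOXA1 replicate 3 (0.0740), siFOXA1+IFNa replicate 2 (0.0800) or siFOXA1+IFNa replicate 3 (0.200), with 0.000748 to 0.200 over all alternatives. PTPN2 lost the call without siFOXA1 replicate 1 (adjusted p = 0.118), siFOXA1 replicate 2 (0.111), siFOXA1 replicate 3 (0.0964), siFOXA1+IFNa replicate 2 (0.0732) or siFOXA1+IFNa replicate 3 (0.192), with 2.9e-05 to 0.192 over all alternatives.

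Smaller shifts after FOXA1 siRNA were seen in other immune lists. Of 12 checkpoint ligand genes 5 rose, among them LGALS9 (4.15 ± 0.28) and CD274 (0.82 ± 0.22), and the list adjusted p was 0.00135 (adjusted p = 0.0815 with an estimated correlation). Of 17 chemokine genes 4 rose, with CCL5, a T cell chemokine, (3.89 ± 0.38) and CXCL11 (1.49 ± 0.22), and CCL2 fell (-0.73); the adjusted p was 0.0208 (adjusted p = 0.0619 with an estimated correlation). TNFSF10 rose by 3.86 ± 0.20 in the cell death list (2 of 22 higher, adjusted p = 0.0372, or an adjusted p of 0.132 with an estimated correlation). The macrophage marker CD68 (0.53), COL1A1 (0.80) and VWF (0.61) rose among the 5 markers of other cell types (adjusted p = 0.0208, or an adjusted p of 0.120 with an estimated correlation). In the cholesterol list 4 of 22 genes rose and 7 fell, with the desaturase SCD (-0.91 ± 0.05) and MSMO1 (-0.43) down and MVD (0.81) up (adjusted p = 0.0372, or an adjusted p of 0.0872 with an estimated correlation). Adjusted over the list alone, 62 type I, 15 MHC class I, 9 signalling, 7 interferon gamma and 6 checkpoint genes rose. The largest decreases included SHROOM1 (-1.97 ± 0.11), HBEGF, an epidermal growth factor receptor ligand, (-1.39 ± 0.10), LEAP2 (-1.63 ± 0.22) and AKR1B10 (-1.04 ± 0.18). Genome-wide 3191 genes were called, 1685 higher and 1506 lower, of which 127 and 30 differed at least 2-fold. The split of directions depended on the scaling, with 2286 higher and 920 lower on TPM and 1262 higher and 1739 lower on quantile-normalised values. It also depended on single libraries, with 323 higher and 583 lower without siFOXA1 replicate 1, 300 and 591 without siFOXA1 replicate 3 and 258 and 495 without siFOXA1+IFNa replicate 3. The count was 906 without siFOXA1 replicate 1, 891 without siFOXA1 replicate 3, 1583 without siFOXA1+IFNa replicate 2 and 753 without siFOXA1+IFNa replicate 3. CCL2 lost the call without siFOXA1 replicate 1 (adjusted p = 0.0818), siFOXA1 replicate 2 (0.0573), siFOXA1+IFNa replicate 1 (0.0568) or siFOXA1+IFNa replicate 3 (0.0919), with 0.00344 to 0.0919 over all alternatives. CD274 lost the call without siFOXA1 replicate 1 (adjusted p = 0.0780), siFOXA1 replicate 2 (0.0648), siFOXA1+IFNa replicate 1 (0.0595) or siFOXA1+IFNa replicate 3 (0.0860), with 0.00148 to 0.0860 over all alternatives. MVD lost the call without siFOXA1 replicate 1 (adjusted p = 0.0589), siFOXA1 replicate 3 (0.0855) or siFOXA1+IFNa replicate 3 (0.0930), with 6.54e-10 to 0.0930 over all alternatives. VWF lost the call without siFOXA1 replicate 1 (adjusted p = 0.109), siFOXA1 replicate 2 (0.0845), siFOXA1 replicate 3 (0.0987), siFOXA1+IFNa replicate 1 (0.0711), siFOXA1+IFNa replicate 2 (0.120) or siFOXA1+IFNa replicate 3 (0.0847), with 0.00811 to 0.120 over all alternatives. The cholesterol list lost the call without siFOXA1 replicate 2 (adjusted p = 0.0544) or siFOXA1+IFNa replicate 2 (0.0608), with 0.0188 to 0.305 over all alternatives. The cell death list lost the call without siFOXA1+IFNa replicate 1 (adjusted p = 0.0563) or siFOXA1+IFNa replicate 2 (0.0608), with 0.0171 to 0.386 over all alternatives. The chemokine list lost the call without siFOXA1+IFNa replicate 2 (adjusted p = 0.0574), with 0.0203 to 0.233 over all alternatives. The other cell types list lost the call without siFOXA1+IFNa replicate 2 (adjusted p = 0.0608), with 0.0135 to 0.189 over all alternatives.

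Whether the interferon response differed with FOXA1 siRNA was tested as an interaction. In the type I interferon list 35 of 64 genes responded more after FOXA1 siRNA and 1, TDRD7 (-0.42), less, with a median log2 interaction of 0.80 and adjusted p = 1.95e-20 (4.42e-06 with an estimated correlation). IFI27 (3.02 ± 0.29), IFITM1 (2.59 ± 0.27), ISG15 (2.55 ± 0.42), DHX58 (2.14 ± 0.24), OAS3 (1.92 ± 0.17) and IFI6 (1.80 ± 0.10) had larger responses, and IRF9 (0.99 ± 0.15) was among 4 of 17 signalling genes (list adjusted p = 0.213). In the MHC class I list 10 of 21 genes responded more, among them HLA-B (0.90 ± 0.12), HLA-C (0.88 ± 0.15) and TAP2 (0.61 ± 0.13), and CANX (-0.36) and PDIA3 (-0.30) less (adjusted p = 4.92e-05, and 0.0380 with an estimated correlation). TNFSF10 had a larger response (2.15 ± 0.31), and SHROOM1 (-1.53 ± 0.16), HBEGF (-1.53 ± 0.15) and DPP4 (-1.10 ± 0.14) had a lower one. In the cell cycle list 1 of 36 genes had a higher and 2 a lower response (adjusted p = 0.788). With p adjusted over the list alone, 38 type I genes and 12 MHC class I genes responded more and 1 and 2 less. CANX lost the call without siCon replicate 2 (adjusted p = 0.0804), siCon replicate 3 (0.0841), siFOXA1 replicate 1 (0.0703), siFOXA1 replicate 3 (0.0708), siCon+IFNa replicate 2 (0.0519), siFOXA1+IFNa replicate 2 (0.0503) or siFOXA1+IFNa replicate 3 (0.0808), with 7.59e-16 to 0.0841 over all alternatives. PDIA3 lost the call without siCon replicate 2 (adjusted p = 0.114), siCon replicate 3 (0.122), siFOXA1 replicate 1 (0.0920), siFOXA1 replicate 2 (0.0550), siFOXA1 replicate 3 (0.0979), siCon+IFNa replicate 2 (0.102), siFOXA1+IFNa replicate 1 (0.0527), siFOXA1+IFNa replicate 2 (0.0696) or siFOXA1+IFNa replicate 3 (0.115), with 8.3e-13 to 0.122 over all alternatives. TAP2 lost the call without siCon replicate 2 (adjusted p = 0.0652), siCon replicate 3 (0.0636), siFOXA1 replicate 1 (0.0607), siFOXA1 replicate 3 (0.0593) or siFOXA1+IFNa replicate 3 (0.0637), with 4.47e-08 to 0.0652 over all alternatives. TDRD7 lost the call without siCon replicate 2 (adjusted p = 0.0956), siCon replicate 3 (0.107), siFOXA1 replicate 1 (0.0924), siFOXA1 replicate 3 (0.0844), siCon+IFNa replicate 2 (0.0906), siFOXA1+IFNa replicate 2 (0.0748) or siFOXA1+IFNa replicate 3 (0.10), with 0.000105 to 0.107 over all alternatives. Genome-wide 3638 interactions were called, 1664 positive and 1974 negative, of which 395 and 27 were at least 2-fold. On TPM there were 1387 positive and 933 negative, and with median-ratio scaling 1600 and 2425. Without a filter there were 1935 and 1730, and in a fit of the compared groups only 1686 and 1532. The balance of signs thus depended on the processing, and not on the scaling alone. The count was 6496 without siCon replicate 1, 134 without siCon replicate 2, 126 without siCon replicate 3, 157 without siFOXA1 replicate 1, 115 without siFOXA1 replicate 3, 888 without siCon+IFNa replicate 2, 1057 without siFOXA1+IFNa replicate 2 and 144 without siFOXA1+IFNa replicate 3. The number of type I genes with a larger response was 18 without siCon replicate 2, 21 without siCon replicate 3, 18 without siFOXA1 replicate 1, 16 without siFOXA1 replicate 3 and 20 without siFOXA1+IFNa replicate 3, and the number with a lower response 2 without siCon replicate 1 or siCon+IFNa replicate 3; the list median stayed between 0.71 and 0.84 when each library was left out in turn.

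The fourth comparison, siFOXA1+IFNa against siCon+IFNa, gives the effect of FOXA1 siRNA under interferon. Over all 16233 genes tested 70.3% were called in it, 50.3% of these higher. Of the 64 type I interferon genes 45 were higher after FOXA1 siRNA and 5 lower, with a median of 0.98 and adjusted p = 7.83e-07 (0.00135 with an estimated correlation). IFI27 (4.01 ± 0.13), BST2 (3.40 ± 0.21), IFI6 (2.67 ± 0.06), IFITM1 (2.59 ± 0.15) and ISG15 (2.89 ± 0.29) were higher, and EIF2AK2 (-0.75), TRIM14 (-0.62), PARP14 (-0.36), HERC5 (-0.31) and ADAR (-0.10) lower. Without siCon+IFNa replicate 3 there were 9 lower type I genes. Of 17 signalling genes 10 were higher and 5 lower, with IRF7 (2.11 ± 0.25) and IRF9 (1.08 ± 0.10) up and JAK2 (-0.80) and IRF1 (-0.92) down (adjusted p = 0.104). In the MHC class I list 16 of 21 genes were higher and 4 lower, with HLA-E (1.33 ± 0.13), TAPBP, which loads peptides, (1.09 ± 0.10) and HLA-B (0.93 ± 0.08) up and TAP2 (-1.09) and ERAP2 (-1.27) down; as a list this did not pass (adjusted p = 0.0734). Of 12 checkpoint genes 8 were higher, such as LGALS9 (3.62 ± 0.26) and CD276 (1.02 ± 0.09), and CD274 (-1.49 ± 0.18) and PVR (-0.48) lower (adjusted p = 0.104). Of 17 chemokine genes 13 were higher and 2 lower, with TRAF1 (4.07 ± 0.25), CXCL11, an interferon-induced T cell chemokine, (3.56 ± 0.28) and CCL5 (5.24 ± 0.45) up (adjusted p = 0.000424, and 0.00706 with an estimated correlation). ADAR lost the call without siCon+IFNa replicate 1 (adjusted p = 0.0824), siCon+IFNa replicate 2 (0.122), siFOXA1+IFNa replicate 1 (0.0749), siFOXA1+IFNa replicate 2 (0.0721) or siFOXA1+IFNa replicate 3 (0.136), with 0.000202 to 0.842 over all alternatives. PARP14 lost the call without siCon+IFNa replicate 1 (adjusted p = 0.0637), with 0.00143 to 0.0637 over all alternatives.

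The lists that moved with FOXA1 siRNA in vehicle moved the same way under interferon. Of 36 cell cycle genes 33 fell and none rose (median -2.03, adjusted p = 6.18e-20), with MKI67 (-2.67 ± 0.09), TOP2A (-2.62 ± 0.10) and CCNB1, cyclin B1, (-1.99 ± 0.08). Of 17 basal and mesenchymal genes 13 rose and 2 fell (median 1.42, adjusted p = 1.76e-06), with FN1 (2.71 ± 0.04) and SNAI2 (3.53 ± 0.17). Of 20 stress genes 12 fell and 3 rose (adjusted p = 0.000424), with the folate enzyme MTHFD2 (-1.40 ± 0.07) and ATF3 (-1.25 ± 0.05), and of 8 forkhead and hepatocyte factor genes 5, with FOXA1 itself among them, fell and 2 rose (adjusted p = 0.0143, with a range of 0.00416 to 0.253 over all alternatives). With an estimated correlation the adjusted p of these lists was 0.00135, 0.00152, 0.00706 and 0.0460. Androgen-regulated genes again split, with 17 higher, such as KLK3 (2.49 ± 0.07) and KLK4 (2.39 ± 0.16), and 20 lower, such as SLC45A3 (-5.41 ± 0.12); the list adjusted p was 0.0475 (adjusted p = 0.0931 with an estimated correlation). The androgen-regulated gene list lost the call without siFOXA1+IFNa replicate 1 (adjusted p = 0.0758), siFOXA1+IFNa replicate 2 (0.0753) or siFOXA1+IFNa replicate 3 (0.0744), with 0.0177 to 0.504 over all alternatives. Adjusted over the list alone, 17 MHC class I and 14 chemokine genes were higher, and 21 androgen-regulated genes, 13 stress genes and 6 signalling genes lower. KRT16 was at least 354-fold higher, and SERPINA5 (7.99 ± 0.28), CRYAB, a small heat shock protein, (6.46 ± 0.14) and KRT14 (6.04 ± 0.42) were among the largest increases. Over the 3 siCon+IFNa libraries SERPINA5 held 4 fragments and KRT14 6, so the sizes of these 2 increases rest on few fragments. ADH1C (-6.09 ± 0.21) was among the largest decreases. In all 11418 genes were called, 5739 higher and 5679 lower, of which 2300 and 1628 differed at least 2-fold; on quantile-normalised values 4560 were higher and 5108 lower. Between the comparisons with and without interferon, which share no library, 3850 genes were higher in both (1737 by chance), 4193 lower in both (1821 by chance) and 93 opposite, and the fold changes correlated across genes with Pearson's r = 0.891 (genes are not independent replicates).

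The fifth comparison, siFOXA1+siSTAT2+IFNa against siFOXA1+IFNa, measures the effect of adding STAT2 siRNA. FOXA1 was also 0.53 ± 0.06 higher there, so loss of STAT2 and a partial return of FOXA1 are not separated in it. Of the 64 type I interferon genes 60 fell and none rose when STAT2 siRNA was added, with a median of -1.61 and adjusted p = 1.6e-155 (6.47e-10 with an estimated correlation). IFI27 dropped from 33.9 ± 4.16 to 1.78 ± 0.0345 CPM, ISG15 from 105 ± 23.6 to 16.2 ± 4.94 and IFI6 from 154 ± 4.43 to 10.4 ± 0.465. OAS2 fell by 5.33 ± 0.21, XAF1 by 5.72 ± 0.24, IFITM1 by 3.84 ± 0.17, BST2 by 3.68 ± 0.21 and OAS3 by 3.63 ± 0.12. Of 17 signalling genes 7 fell, with IRF9 (-1.81 ± 0.10) and IRF7 (-1.25 ± 0.24) beside STAT2, the siRNA target, whose fall restates the knockdown, and PTPN2, a protein tyrosine phosphatase, rose (0.40 ± 0.07). The list adjusted p was 5.56e-05 (0.00324 with an estimated correlation), and this list was not tested without STAT2. Of 21 MHC class I genes 15 fell and none rose, with PSMB9 (-2.22 ± 0.28), HLA-B (-1.56 ± 0.08) and HLA-C (-1.08 ± 0.11) (adjusted p = 3.74e-09, and 0.00283). Of 14 interferon gamma genes 7 fell, such as GBP4 (-2.80 ± 0.26) and WARS, a tryptophan tRNA synthetase, (-0.64 ± 0.04) (adjusted p = 0.000259, and 0.0165). TNFSF10 (-3.39 ± 0.18), LGALS9 (-3.14 ± 0.25), CD274 (-1.76 ± 0.25) and CCL5 (-2.26 ± 0.31) fell as well, the checkpoint list having 2 of 12 genes lower (adjusted p = 0.0273, or an adjusted p of 0.157 with an estimated correlation) and the chemokine list 5 of 17 lower and 1, CCL2 (0.59), higher (adjusted p = 0.0166, and 0.0417). CCL2 lost the call without siFOXA1+IFNa replicate 1 (adjusted p = 0.112), siFOXA1+IFNa replicate 3 (0.0978), siFOXA1+siSTAT2+IFNa replicate 1 (0.0736) or siFOXA1+siSTAT2+IFNa replicate 3 (0.143), with 0.0147 to 0.143 over all alternatives. The checkpoint list lost the call without siFOXA1+siSTAT2+IFNa replicate 3 (adjusted p = 0.0533), with 0.00959 to 0.280 over all alternatives.

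Cell cycle genes moved the other way when STAT2 siRNA was added. Of 36 genes 24 rose and 2 fell, with a median of 0.80 and adjusted p = 5.04e-13 (0.00151 with an estimated correlation). RRM2 went from 2.38 ± 0.169 to 6.29 ± 0.501 CPM, against 21.3 ± 3.10 in siCon+IFNa, TOP2A rose by 1.12 ± 0.10 and CCNB1 by 0.85 ± 0.08, while the replication helicase genes MCM4 (-0.68) and MCM3 (-0.19), the latter named after its value was seen, fell. Of 20 stress genes 14 fell and none rose, with PHGDH, a serine synthesis enzyme, (-0.81 ± 0.11), TRIB3 (-0.47 ± 0.05) and PSAT1 (-0.44 ± 0.05) (adjusted p = 1.67e-06, and 0.00151). Of 22 cholesterol and lipid genes 9 fell and 3 rose, with SCD (-0.51 ± 0.05) and ACLY (-0.43 ± 0.06) down (adjusted p = 0.0166, and 0.0471). Of 24 luminal genes 10 fell, such as XBP1 (-0.37 ± 0.05) and KRT18 (-0.53 ± 0.08), and 2 rose (adjusted p = 0.0365, or an adjusted p of 0.156 with an estimated correlation). Of 16 hypoxia genes 7 fell, such as HK2 (-0.60 ± 0.06), and 1, PDK1 (0.33), rose (adjusted p = 0.0441, or an adjusted p of 0.0783 with an estimated correlation). Of the androgen-regulated genes 9 were higher and 7 lower, and FAS, a death receptor, rose by 0.70 ± 0.08 in a p53 list with 4 higher and 5 lower. MCM3 lost the call without siFOXA1+IFNa replicate 1 (adjusted p = 0.0912), siFOXA1+IFNa replicate 2 (0.0504), siFOXA1+IFNa replicate 3 (0.162), siFOXA1+siSTAT2+IFNa replicate 1 (0.107), siFOXA1+siSTAT2+IFNa replicate 2 (0.117) or siFOXA1+siSTAT2+IFNa replicate 3 (0.0612), with 0.00109 to 0.162 over all alternatives. The hypoxia list lost the call without siFOXA1+IFNa replicate 1 (adjusted p = 0.0579), siFOXA1+IFNa replicate 2 (0.0529) or siFOXA1+siSTAT2+IFNa replicate 1 (0.0531), with 0.0132 to 0.362 over all alternatives. The luminal list lost the call without siFOXA1+IFNa replicate 3 (adjusted p = 0.0616) or siFOXA1+siSTAT2+IFNa replicate 3 (0.0533), with 0.00346 to 0.156 over all alternatives. Adjusted over the list alone, 26 cell cycle genes rose and 3 fell, and 62 type I, 16 MHC class I and 16 stress genes fell.

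In all 5179 genes were called in this comparison, 2631 higher and 2548 lower, of which 163 and 134 differed at least 2-fold. The share of called genes that were higher, 50.8%, depended on the scaling and was 25% on TPM and 34.3% with limma on log2(FPKM + 1). The largest increases included the small nucleolar RNA genes SNORD12 (2.42 ± 0.47), SNORD83A (1.54 ± 0.27) and SNORD28 (1.43 ± 0.36), with SLC6A16 (1.68 ± 0.17), CD37 (1.49 ± 0.16) and the centromere histone CENPA (1.47 ± 0.18). How fragments of small RNAs inside host genes were counted is not given in the sources used here, so the values of the SNORD rows in this paragraph may hold fragments of their host genes. Of the genes higher in siFOXA1+IFNa than in siCon+IFNa, 1596 were lower again with STAT2 siRNA, led by IFI27, BST2, LGALS9, ISG15, IFI6, IFITM1, CCL5, OAS2, OAS1 and RSAD2. In the other direction 1763 genes went from lower to higher, led by SNORD12, FKBP1B, CYP4F62P, SNORD77, CENPA, NMU, SNORD28, MTFR2, DLGAP5 and RRM2. Unrelated lists of the same sizes would share 901 and 920, a value that leaves out the shared siFOXA1+IFNa libraries; 20 simulations of unchanged groups gave 0, a value set by the absence of any change. The covariance of the fold changes across genes was -0.176, against -0.0203 in the simulations, and Pearson's r was -0.364, which is less negative than the -0.492 of the simulations, where fold changes hold noise alone. Both comparisons use the siFOXA1+IFNa libraries, which by itself relates their fold changes negatively, and these could not be divided, so part of the excess over unrelated lists may come from them. FOXA1 was itself 0.53 ± 0.06 higher with STAT2 siRNA, so the reversal counts do not separate loss of STAT2 from a partial return of FOXA1. CYP4F62P lost the call without siFOXA1+IFNa replicate 2 (adjusted p = 0.0939) or siFOXA1+siSTAT2+IFNa replicate 2 (0.0780), with 0.00640 to 0.819 over all alternatives. NMU lost the call without siFOXA1+IFNa replicate 2 (adjusted p = 0.0723) or siFOXA1+siSTAT2+IFNa replicate 3 (0.0570), with 0.00842 to 0.184 over all alternatives. FKBP1B lost the call without siFOXA1+IFNa replicate 3 (adjusted p = 0.0606), siFOXA1+siSTAT2+IFNa replicate 1 (0.0767) or siFOXA1+siSTAT2+IFNa replicate 2 (0.0580), with 0.00167 to 0.0767 over all alternatives. On quantile-normalised values the change of CYP4F62P with STAT2 siRNA was -0.021.

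The sixth comparison, siFOXA1+siSTAT2+IFNa against siCon+IFNa, sets the double knockdown beside control cells under interferon. Over all 16233 genes tested 65.7% were called in it, 51.1% of these higher. Of the 64 type I interferon genes 40 were lower than in siCon+IFNa and 6 higher, with a median of -0.82 and adjusted p = 7.12e-09 (0.000275 with an estimated correlation). OAS2 (-3.07 ± 0.23), IFIT2 (-2.91 ± 0.09), OAS3 (-2.57 ± 0.11) and DDX58 (-2.30 ± 0.11) were lower and UBA7, the activating enzyme for ISG15, (1.12 ± 0.17) and IFITM2 (0.75 ± 0.17) higher. Without siFOXA1+siSTAT2+IFNa replicate 1 there were 3 higher type I genes. IRF9 (-0.74 ± 0.11) and CD274 (-3.25 ± 0.22) were lower, and HLA-B (-0.64 ± 0.09) and HLA-C (-0.44 ± 0.11) were among 7 lower and 7 higher of 21 MHC class I genes (adjusted p = 0.766). Of 36 cell cycle genes 34 were lower, with MKI67 at -1.77 ± 0.09 and a median of -1.20 (adjusted p = 7.54e-12, and 0.000799 with an estimated correlation). Of 17 basal and mesenchymal genes 13 were higher and 1, ITGA5 (-1.08), lower, with FN1 at 2.89 ± 0.04 (adjusted p = 1.99e-08, and 0.000519), and of 17 chemokine genes 12 were higher and 3 lower (adjusted p = 0.00489, and 0.0191). Of 20 stress genes 16 were lower and none higher, with DDIT3 at -1.41 ± 0.06 and TRIB3 at -1.30 ± 0.05 (adjusted p = 1.75e-09, and 0.000356). Androgen-regulated genes were lower as a list (16 higher, 19 lower, median -0.03, adjusted p = 0.00364, and 0.0154 with an estimated correlation, in a range of 0.00121 to 0.622 over all alternatives), with SLC45A3 (-5.31 ± 0.12) down and KLK3 (2.42 ± 0.07) up, as were 5 of 8 forkhead and hepatocyte factor genes, with FOXA1 itself among them (adjusted p = 0.00153, and 0.0154; over all alternatives, 0.000507 to 0.118). There were 41 lower type I genes adjusted over the list alone. KRT16 was at least 82.6-fold higher. In all 10668 genes were called, 5447 higher and 5221 lower, of which 1953 and 1315 differed at least 2-fold; on TPM 4158 were higher and 4923 lower.

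**Figure D2:**
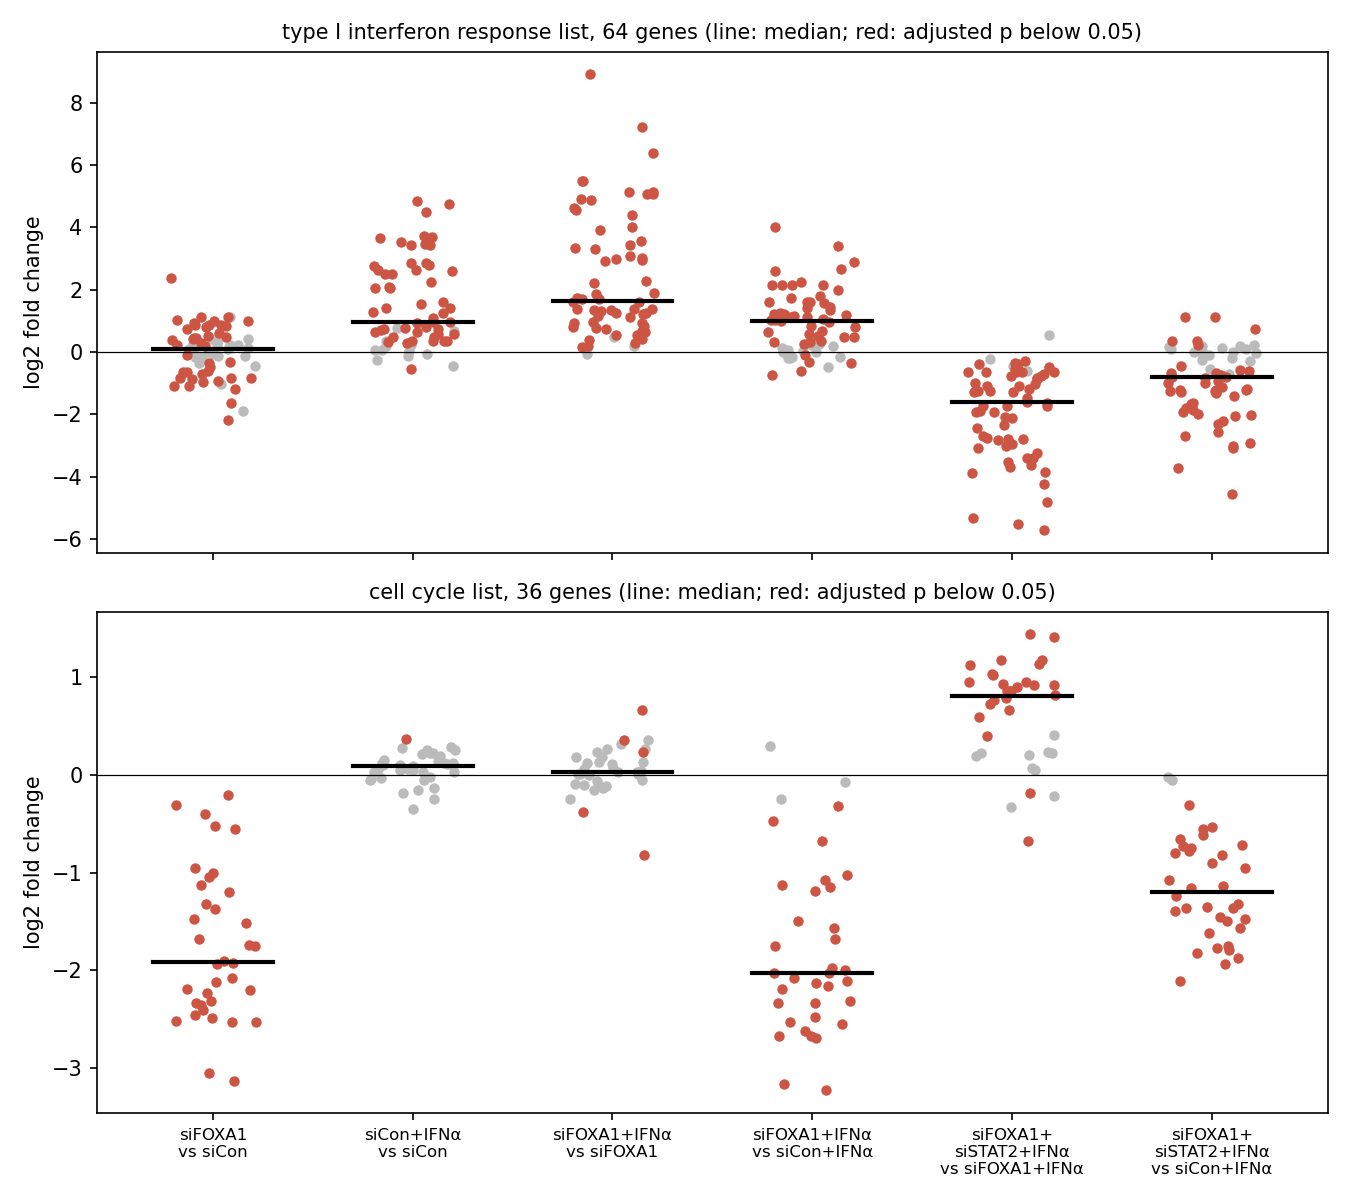
log2 fold change (vertical axis) of each tested gene of the type I interferon list (64 genes) and the cell cycle list (36 genes) in the 6 comparisons; red points have an adjusted p under 0.05 and lines are medians. The type I median is 0.95 with interferon in siCon cells, 1.65 after FOXA1 siRNA and -1.61 when STAT2 siRNA is added, and the cell cycle median is -1.91 after FOXA1 siRNA, -2.03 under interferon and 0.80 when STAT2 siRNA is added.

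**Figure D3:**
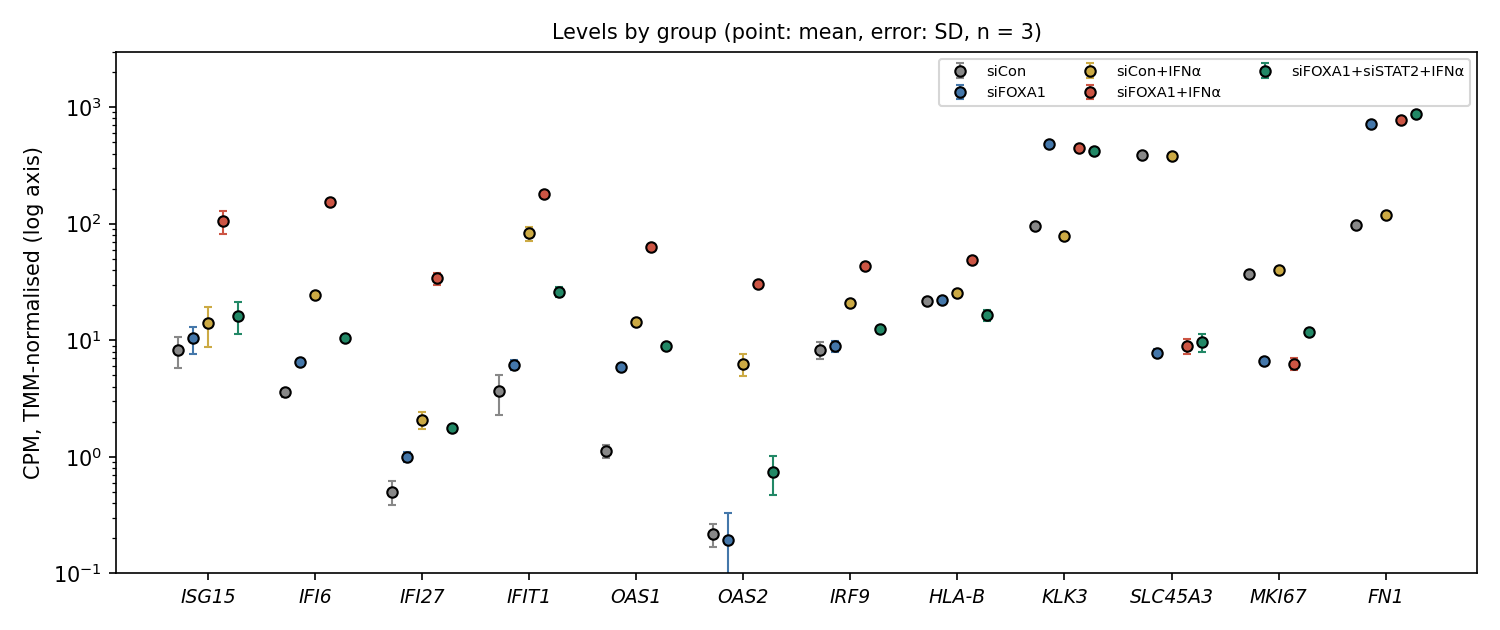
TMM-normalised CPM (vertical axes, log scale) of 12 genes in the 5 groups; points are group means and error bars are SD (n = 3). ISG15 and IFI27 are highest in siFOXA1+IFNa, KLK3 is higher and SLC45A3 lower in the 3 groups with FOXA1 siRNA, and MKI67 is lowest in siFOXA1 and siFOXA1+IFNa.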

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

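The tests of the library that stands apart, of gene length, of the shared axis and of list members called in other splits were chosen after the result was seen; the other counts of splits were planned. The response to interferon differed between cells with and without FOXA1 siRNA by a test of the interaction itself in 3638 genes. This count was 6496 without siCon replicate 1, 134 without siCon replicate 2, 126 without siCon replicate 3, 157 without siFOXA1 replicate 1, 115 without siFOXA1 replicate 3, 888 without siCon+IFNa replicate 2, 1057 without siFOXA1+IFNa replicate 2 and 144 without siFOXA1+IFNa replicate 3. The median log2 interaction was 0.80 in the type I interferon list (adjusted p = 1.95e-20), 0.49 in the MHC class I list (4.92e-05), -0.28 in the cholesterol list (0.0404) and 0.71 in the list of other cell types (0.0133). For the last 2 lists the adjusted p was 0.136 and 0.166 with an estimated correlation. The cholesterol list lost the call without siCon replicate 1 (adjusted p = 0.0752), siFOXA1 replicate 2 (0.0736), siCon+IFNa replicate 3 (0.0558), siFOXA1+IFNa replicate 1 (0.0513) or siFOXA1+IFNa replicate 2 (0.0635), with 0.0111 to 0.299 over all alternatives.

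Single genes with a larger response after FOXA1 siRNA were XAF1 (log2 interaction 4.18), IFI27 (3.02), ODF3B (2.94), IFITM1 (2.59), ISG15 (2.55), OAS2 (2.39), MIR6805 (2.36), BST2 (2.28), TNFSF10 (2.15) and DHX58 (2.14). Over the 3 siFOXA1 libraries XAF1 held 2 fragments, OAS2 18 and BST2 32. The sizes and ranks of these interactions therefore rest on few fragments. Genes with a lower response were FKBP1B (-1.82), SHROOM1 (-1.53), HBEGF (-1.53), ITGB8 (-1.34), LEAP2 (-1.31), PLIN2 (-1.30), LRRC31 (-1.29), DPP4 (-1.10) and MIR4657 (-1.06). How fragments of small RNAs inside host genes were counted is not given in the sources used here, so the values of MIR6805 and MIR4657 were not told apart from those of any host gene. OAS2 lost the call without siCon replicate 2 (adjusted p = 0.0708), siCon replicate 3 (0.0915), siFOXA1 replicate 1 (0.0667), siFOXA1 replicate 3 (0.0680) or siFOXA1+IFNa replicate 3 (0.0644), with 7.41e-07 to 0.0915 over all alternatives. MIR6805 lost the call without siCon replicate 2 (adjusted p = 0.0746), siCon replicate 3 (0.0763), siFOXA1 replicate 1 (0.0637), siFOXA1 replicate 3 (0.0669) or siFOXA1+IFNa replicate 3 (0.0728), with 1.46e-08 to 0.0763 over all alternatives. BST2 lost the call without siCon replicate 2 (adjusted p = 0.117), siCon replicate 3 (0.0915), siFOXA1 replicate 1 (0.0688), siFOXA1 replicate 3 (0.0593) or siFOXA1+IFNa replicate 3 (0.0748), with 2.83e-06 to 0.117 over all alternatives. FKBP1B lost the call without siCon replicate 2 (adjusted p = 0.0862), siCon replicate 3 (0.0902), siFOXA1 replicate 1 (0.0709), siFOXA1 replicate 2 (0.0834), siFOXA1 replicate 3 (0.0997), siCon+IFNa replicate 2 (0.0879), siFOXA1+IFNa replicate 1 (0.0597), siFOXA1+IFNa replicate 2 (0.0613) or siFOXA1+IFNa replicate 3 (0.112), with 0.00923 to 0.112 over all alternatives. ITGB8 lost the call without siCon replicate 2 (adjusted p = 0.0792), siCon replicate 3 (0.0811), siFOXA1 replicate 1 (0.0643), siFOXA1 replicate 3 (0.0663) or siFOXA1+IFNa replicate 3 (0.0729), with 0.00166 to 0.172 over all alternatives. LEAP2 lost the call without siCon replicate 2 (adjusted p = 0.0740), siCon replicate 3 (0.0748), siFOXA1 replicate 1 (0.0688), siFOXA1 replicate 3 (0.0649), siCon+IFNa replicate 2 (0.0690), siFOXA1+IFNa replicate 2 (0.0504) or siFOXA1+IFNa replicate 3 (0.0737), with 0.00207 to 0.0748 over all alternatives. LRRC31 lost the call without siCon replicate 2 (adjusted p = 0.0844), siCon replicate 3 (0.0862), siFOXA1 replicate 1 (0.0733), siFOXA1 replicate 2 (0.0679), siFOXA1 replicate 3 (0.0722), siCon+IFNa replicate 2 (0.0691), siFOXA1+IFNa replicate 1 (0.0682) or siFOXA1+IFNa replicate 3 (0.10), with 0.00106 to 0.274 over all alternatives. MIR4657 lost the call without siCon replicate 2 (adjusted p = 0.0800), siCon replicate 3 (0.0836), siFOXA1 replicate 1 (0.0652), siFOXA1 replicate 3 (0.0743), siCon+IFNa replicate 2 (0.0620), siFOXA1+IFNa replicate 2 (0.0515) or siFOXA1+IFNa replicate 3 (0.0748), with 0.00186 to 0.0836 over all alternatives. ODF3B lost the call without siCon replicate 3 (adjusted p = 0.0600) or siFOXA1 replicate 3 (0.0508), with 1.5e-07 to 0.0600 over all alternatives. XAF1 lost the call without siFOXA1 replicate 1 (adjusted p = 0.0582) or siFOXA1 replicate 3 (0.0593), with 7.41e-07 to 0.0593 over all alternatives. PLIN2 lost the call without siFOXA1 replicate 3 (adjusted p = 0.0527), with 4.28e-06 to 0.0527 over all alternatives.

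The larger response of the type I interferon list (median 0.80) was set against 3 technical explanations. The median was 0.71 without siCon+IFNa replicate 2, which stands apart from its group (adjusted p = 1.6e-28). It was 0.73 with the gene length trend of each library removed (3.45e-22), and neither took the list below its threshold. With the first residual factor, the main axis of variation within groups, as a covariate the median was 0.81 (adjusted p = 4.06e-10). That factor was built from deviations from the group means, so it could not remove a difference between groups and does not decide on this explanation. In 100 permutations of the interferon labels within each siRNA arm, 3, the real grouping among them, gave as many called genes as the real 3638 (highest other 5940, median other 0). The other 2 exchange the labels of the whole siFOXA1 arm and also place siCon+IFNa replicate 2 with siCon replicate 1, and these were not tested apart. Splits that mix treated and untreated libraries put the interferon response into the spread within groups, so this count does not decide on chance for the interaction. In 37 permutations the list median was as large (highest other 1.95) and in 6 as many members were called (36, highest other 53), so chance is not excluded for the list by this test, in which exchanging labels in 1 arm turns part of the interferon response itself into an interaction. A larger response after loss of FOXA1, which the design names, may account for the pattern as a hypothesis, and an off-target effect of the siRNA stays open because no second siRNA is among the groups.

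The 6 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes as were called with edgeR, and the highest other split gave 0. The absolute median of the type I list was as large in 1 split of each, with real values of 0.11, 0.95, 1.65, 0.98, 1.61 and 0.82 in the order of the comparisons without the interaction, and highest others of 0.10, 0.38, 0.55, 0.31, 0.54 and 0.36. Every other split of a comparison mixes libraries of both groups. Mixing puts a difference between the groups into the spread within them and shrinks the medians. These splits therefore do not decide on chance for the 6 comparisons. For the reversal, 3 of 100 permutations of 9 libraries, the real grouping among them, gave as many genes in each direction, and the median other gave 0. Splits that mix the groups put the effect of FOXA1 siRNA into the spread within groups, so this test does not decide on chance for the reversal. The highest others, 4410 and 4545 against 1596 and 1763, exchange whole groups, and 1 that mixes groups gave 4295.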

How the results depend on the processing

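The residual factor, the gene length correction and the leaving out of 3 libraries far from their replicates (siCon replicate 1, siCon+IFNa replicate 2 and siFOXA1+siSTAT2+IFNa replicate 3) were chosen after seeing the data. The counts with FOXA1 siRNA in vehicle and under interferon, with STAT2 siRNA and in the double knockdown stayed within 1.5 times when each library was left out in turn. Without 1 library the count ranged from 375 to 3439 in siCon+IFNa vs siCon, from 753 to 2495 in siFOXA1+IFNa vs siFOXA1 and from 115 to 6496 in the interaction. With a mean of at least 5 FPKM, where fewer genes were tested, 5502 genes were called for siFOXA1 vs siCon, 6265 for siFOXA1+IFNa vs siCon+IFNa, 5773 for siFOXA1+siSTAT2+IFNa vs siCon+IFNa and 2329 in the interaction. With replicate number as a block the counts were 891 in siCon+IFNa vs siCon, 1802 in siFOXA1+IFNa vs siFOXA1 and 356 in the interaction. Correlations gave no sign that the numbers pair the libraries, since 12 of 30 same-number pairs had a correlation over 0.1 and the median correlation was -0.39. A weak pairing beneath the main axis of variation within groups may not show in them. The siCon+IFNa vs siCon count was 2854 with limma on log2(FPKM + 1), 2776 with a pseudocount of 0.1 and 70 in a fit of the compared groups only, where siFOXA1+IFNa vs siFOXA1 gave 6235. On TPM the interaction gave 2320 and the reversal 2659 and 992, and with at least 1 log2 unit in both comparisons, a stricter demand, the reversal gave 84 and 104. With the residual factor as a covariate the counts were 7038, 8031, 8986 and 8688 for siCon+IFNa vs siCon, siFOXA1+IFNa vs siFOXA1, siFOXA1+siSTAT2+IFNa vs siFOXA1+IFNa and the interaction, and 3205 and 2730 for the reversal. This factor was built from deviations from the group means, so it can take up spread within groups but not differences between them. Ranges over all alternatives include this fit. Leaving out the 3 libraries gave 3636, 6799 and 6680 for siCon+IFNa vs siCon, siFOXA1+IFNa vs siFOXA1 and the interaction. Where fewer genes or libraries or a stricter demand do not show it, the cause was not tested. The direction of the type I list test in siFOXA1 vs siCon, which did not pass, turned with the residual factor (median 0.13) and without the 3 libraries (0.22); the median was 0.077 to 0.22 when 1 library was left out. CYP4F62P with STAT2 siRNA turned on quantile-normalised values (-0.021). The shares of called genes that were higher depended on the processing: for siFOXA1+siSTAT2+IFNa vs siFOXA1+IFNa 25% on TPM, where the median of all genes shifted by -0.131, against 50.8%, for siFOXA1+IFNa vs siFOXA1 71.3% on TPM against 52.8%, and for the interaction 59.8% on TPM against 45.7%. The TPM fit also changed the test, to limma, and the number of genes tested, to 13072. For the interaction the share was 52.8% without a filter as well. The type I list kept its direction and adjusted p under 0.05 in the other comparisons and the interaction in all alternatives but DESeq2, with which no list was tested, with a median interaction of 0.64 to 0.88. Of 398 other results, single genes and lists, 332 kept their direction and side of the threshold in each leave-one-out setting and 64 lost their call in at least 1. Of those with a value, 30 of 398 lost their call with the block, 29 of 393 in the fit of compared groups, 30 of 370 on quantile-normalised values, 26 of 370 on TPM, 18 of 398 without a filter and 2 of 341 with DESeq2. Many of these results were picked because they were called in the main fit, often with the largest changes. These shares therefore do not carry over to all called genes. At this depth genes under the filter, 10573 rows, were not tested, and a change below the floor of 3 fragments was not detectable.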

Other observations

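Of the tests in this part, the one of the fall of type I interferon genes with STAT2 siRNA, the one of the interferon effect on the cell cycle and the share of the fall under interferon were chosen after the result was seen; the test of FOXA1 restoration on the cell cycle with the fall in vehicle was not. Some groups described above only as lists hold genes with large changes. KRT19, a keratin of simple epithelia, was higher after FOXA1 siRNA under interferon by 5.22 ± 0.31, and HOXB13 by 1.13 ± 0.07. Of 9 neuroendocrine genes 4 were higher and 4 lower in that comparison, with SYT4, a synaptotagmin, going from 6.88 ± 0.920 to 126 ± 8.07 CPM and ONECUT2 falling by 1.44. MX1, an interferon-induced antiviral GTPase, was hardly detected at a mean of 0.466 FPKM and passed in none of the comparisons (log2 change 0.20 ± 0.23 with interferon after FOXA1 siRNA), whereas MX2 rose by 5.48 ± 0.40 there and fell by 4.81 ± 0.36 with STAT2 siRNA. The aldo-keto reductase genes AKR1C1 (-0.95 ± 0.13) and AKR1C2 (-0.97 ± 0.13), which are close paralogs, fell with interferon after FOXA1 siRNA. Across genes, the interferon responses with and without FOXA1 siRNA, which share no library, shared 144 higher genes (117 by chance) and 98 lower genes (54.7 by chance), with 50 opposite and Pearson's r = 0.0871. Genes are not independent replicates. Of the 64 type I interferon genes 50 were higher with interferon in siCon cells and 61 after FOXA1 siRNA. That list thus makes up part of the shared higher genes, and the overlap without it was not counted. The first principal component separated FOXA1 siRNA from siCon and held 80.1% of the variance, and 31.7% of the variance within groups lay on 1 axis.

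The type I interferon list fell when STAT2 siRNA was added, while FOXA1 was partly restored (0.53 ± 0.06). If the return of FOXA1 were the whole cause, the list would lie at or above its siCon+IFNa level, but its median in the double knockdown was -0.82 against siCon+IFNa (quartiles -1.65 and -0.03), which argues against it. A need for STAT2 remains a candidate explanation, with no STAT2 siRNA alone and no second siRNA to test it.

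Cell cycle genes partly returned when STAT2 siRNA was added. Return of FOXA1 alone predicts that they recover as other genes do, but the rise of the 30 cell cycle genes that FOXA1 siRNA lowered at least 2-fold in vehicle was a median of 37.7% of that fall, a share that sets a rise under interferon beside a fall without it so that no library is shared, against 16.0% for 1501 other fallen genes, 8.73% for 1564 risen genes and 4.68 to 28.3% in the middle 95% of 10000 random lists of fallen genes matched for the size of the fall (percentile 99.98). With the fall under interferon, which shares the siFOXA1+IFNa libraries, the cell cycle share was 38.4%, against 18.98% for 1595 other fallen genes and 8.10 to 31.5% in random lists. The random lists hold genes drawn singly, whereas cell cycle genes may move together, so the percentile does not measure the spread between libraries. For FOXA1 itself the shares were 30.9% and 25.5%, so cell cycle genes that respond more steeply to FOXA1 stay open. Removal of an effect of interferon on the cell cycle fails as the whole cause, because the list changed by a median of 0.031 with interferon after FOXA1 siRNA (quartiles -0.07 and 0.18). An effect of STAT2, or of its siRNA on other targets, may account for the rest; without a group with STAT2 siRNA alone they were not separated.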
